A study of Mus musculus with 6 samples.

How the data were processed

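RNA from 6 pools of NIH3T3 mouse embryonic fibroblasts was analysed, 3 transduced with pBabe-Puro and 3 with pBabe-Puro carrying c-srcY527F. Per the labels' protocols, cells grew in RPMI with 10% FCS and non-essential amino acids, total RNA was extracted with a column kit, and libraries were made with an Illumina mRNA-Seq kit. The design text describes independent cultures for the 3 pools of a group. Groups and replicate numbers were taken from the sample titles.

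The processed file is a table with 1 row per gene symbol. Per the file headers, the authors' values are RPKM, reads per kilobase of gene model and M (mega, as in CPM) mapped reads, 1 column per library. Per the submitters' processing notes, CASAVA and the mm9 assembly were used. The mapping and counting tools, their versions, the gene annotation and the treatment of reads that match several places are not given in the sources used here. The authors' deposited table also holds, per the file headers, a signed fold change of the group means (a score without a fixed range) and an unadjusted p-value of a comparison of the groups. Recomputed from the 6 RPKM columns, a pooled-variance comparison on untransformed RPKM gave the deposited p-value for 17829 of 17829 genes within 1e-06. In the authors' deposited table, 6954 of 35495 genes had a p-value under 0.05, 3823 with a positive and 3131 with a negative fold. Among the 10839 genes tested here, 5730 had such a p-value, 4417 after Benjamini-Hochberg adjustment, and 5199 of the 5730 were also called by limma.

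RPKM values are not counts, but the read numbers behind them could be recovered. Within a gene the 6 RPKM values stand in ratios of whole reads, scaled by the depth of each library. The depth of each library, the length of each gene model and the reads per gene were solved from these ratios. For 100% of the 17829 genes with a value, all 6 values came within 0.01 of a whole read. On simulated tables of 3901 genes the same steps returned the exact reads for 97.4% of genes, the reads up to a common factor for 100%, and the depth with an error of 0 reads. Recovered depths were 126.4, 141.9, 89.4, 161.3, 149.2 and 121.9 M mapped reads for vector 1 to 3 and src 1 to 3. Recovered reads were used for depth, for shares and numbers of reads, for reads per M mapped reads (CPM) in the rule for named genes, for alternatives, and for comparing and thinning libraries, but not for the main test.

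The design fixed before the data were examined assumed a table of counts and named a count model, with limma on log2(RPKM + 1) where the file held no counts. Since the file holds RPKM, the main test was limma 3.58.1 in R 4.3.3, with a mean-variance trend, on log2(RPKM + 1), with group as the only term. DESeq2 was not used. The design set no filter for RPKM. Genes with at least 0.5 RPKM in at least 3 libraries were tested, a filter set after the file had been seen, which left 10839 genes. P-values were adjusted by the Benjamini-Hochberg method with a threshold of 0.05. Fold changes are on the log2(RPKM + 1) scale, which understates the change of genes with low values. A change written without a unit, or as a number in brackets after a gene, is this log2 fold change of src against vector. Means are given with the SD over the 3 libraries of a group. The test was tried on simulated reads for the comparison of src with vector, with 10699 genes after the filter and known changes. It called 53.7% of 1.5-fold, 92.5% of 2-fold and 93.9% of 4-fold changes, 3.6% of its calls were unchanged genes, and 0 gene lists were called. The simulated spread was independent between genes and between libraries. These values therefore do not cover lists of correlated genes or replicates that are not independent.

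Gene lists were written from textbook knowledge before the data were examined: 4 of sphingolipid metabolism, and lists of cholesterol synthesis, fatty acid synthesis, glycolysis, extracellular matrix, matrix proteolysis, contractile genes, YAP targets, ERK-driven and immediate early genes, Src family and adhesion, integrins, cadherins and junctions, cell cycle, interferon response, cytokines and growth factors, unfolded protein and amino acid responses, hypoxia, p53 targets, lysosome and autophagy, and markers of 7 other cell types, 28 in all. Older symbols were matched to those of the table, so that ceramide synthases appear as Lass genes and lipid phosphate phosphatases as Ppap2 genes. Lists with at least 3 tested genes were compared with all other genes by limma camera, two-sided, with a preset inter-gene correlation of 0.01 and Benjamini-Hochberg adjustment over the lists. Camera with an estimated correlation is given beside each list that passed, and none of the 5 lists held its call with it. The preset value takes genes of a list as nearly independent, so that its p-values are too small where they are not. The estimated correlations were 0.33, 0.37, 0.54 and 0.14 for extracellular matrix, cholesterol synthesis, glycolysis and ERK-driven genes. For the unfolded protein and amino acid responses it was -0.01, below the preset value. Correlated genes therefore do not account for the loss of that call. Terms of the biological process annotation in the deposited table, with 15 to 300 tested genes, were tested the same way after the data had been seen.

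The genes named in the text follow a rule fixed before the data were examined. They are Src, the 10 largest rises and the 10 largest falls among called genes (with at least 5 CPM in the higher group, no overlap of the groups, and no predicted genes), and any tested sphingolipid gene. From each other list come up to 5 genes with the smallest adjusted p in each direction and up to 2 with the highest level that did not pass, and the 5 most abundant genes may be named where shares of reads are given. Genes outside this rule are said to be so, and a few results that fall under it are not reported here.

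Alternatives fixed beforehand were median-of-ratios and upper-quartile scaling, limma voom on the recovered reads, a pseudocount of 0.1, no filter, a stricter filter (planned as 5 CPM, run as at least 5 RPKM in 3 libraries), the replicate number as a block, each library left out, each replicate number left out, a minimum fold change of 1.2 (run with limma treat), removal of trends with gene length and GC content, an estimated inter-gene correlation and the fry rotation test. Trimmed mean of M-values scaling and a fit with vector 1 and 2 averaged as 1 replicate were added after seeing the data. GC content came from the GRCm38 annotation by gene symbol, for 98.6% of tested genes. No coordinates are given, since the reference at hand is of another assembly than mm9. Python 3.11.15 with numpy 2.4.6, scipy 1.17.1, pandas 2.3.3 and matplotlib 3.10.9 was used for the recovery of reads and the figures.

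With 3 libraries against 3, the 10 possible splits of the libraries cannot give a share under 0.1, so p-values rest on limma's model of the spread. The recovered reads of vector 1 and 2 differed with a chi-square per gene of 3.47 over 13364 genes, against 80.0 and 86.2 for the pairs with vector 3. They were kept as separate replicates because the design text describes independent cultures. If they are not independent, the p-values are too small.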

Results

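Messenger RNA was measured by sequencing in NIH3T3 cells, an immortalized line of mouse embryonic fibroblasts. The cells carried either the empty retroviral vector pBabe-Puro (called vector below) or the same vector with c-srcY527F (called src). This form of the Src tyrosine kinase lacks the C-terminal tyrosine through which Src is held inactive, and it transforms fibroblasts. Each group held 3 libraries, numbered 1 to 3, made from pools of transduced cells after 7 days of puromycin selection. The reads behind the deposited values numbered 126.4, 141.9 and 89.4 M in vector 1, 2 and 3, and 161.3, 149.2 and 121.9 M in src 1, 2 and 3. Of these, 87.2% to 89.8% fell in the genes of the table. The table listed 35495 genes, of which 17829 had a value above 0 in at least 1 library and 10839 were tested.

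The Src transcript was higher in every src library than in every vector library. It stood at 18.6 ± 4.29 RPKM (SD, n = 3) in vector and at 52.1 ± 12.5 RPKM (SD, n = 3) in src, a ratio of 2.8. The single libraries held 16.2, 16.1 and 23.6 RPKM in vector and 64.0, 39.0 and 53.3 RPKM in src. On the log2(RPKM + 1) scale the change was 1.43 (SE 0.21, limma adjusted p = 0.0022). Reads from the mouse gene and from the construct cannot be told apart in these values, and the species of the construct is not given in the sources used here.

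The groups separated along the first principal component, which held 83.6% of the variance of the tested genes. Vector 1 and 2 lay at -31.9 and -31.2 on it, vector 3 at -19.4, and the src libraries between 27.4 and 27.7. Vector 1 and 2 correlated across genes with r = 0.9993, the highest value of any pair, and vector 3 correlated with them with r = 0.9914 and 0.9926. Vector 3 also correlated more closely with the src libraries (r from 0.962 to 0.9658) than vector 1 and 2 did (r from 0.9462 to 0.9516). Src 2 stood apart from src 1 and 3 on the second component, which held 9.4% of the variance.

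**Figure D1:**
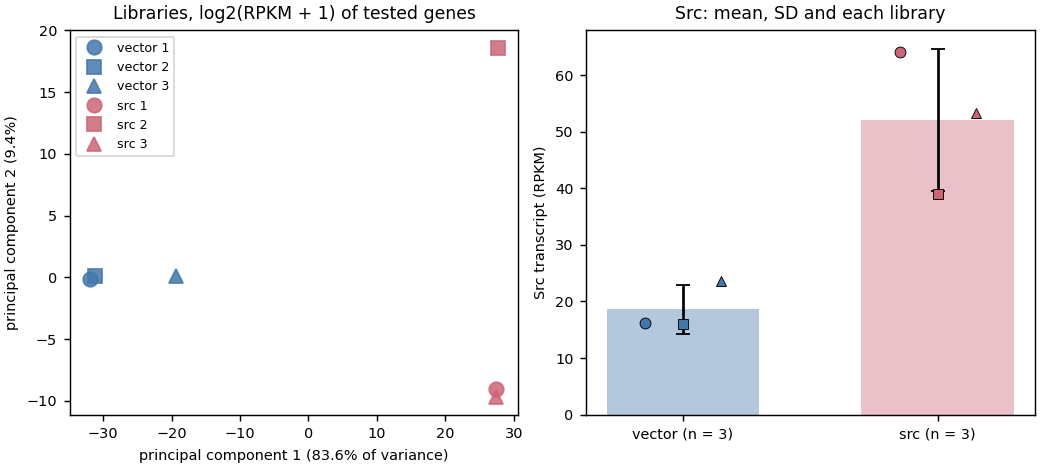
Left, the 6 libraries on the first and second principal components of log2(RPKM + 1) of the tested genes. Right, the Src transcript in RPKM, with bars for the mean, error bars for the SD and points for single libraries; the src libraries lie between 39.0 and 64.0 RPKM and the vector libraries between 16.1 and 23.6 RPKM.

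Src changed the level of a large part of the fibroblast transcriptome. Proliferin transcripts, the RhoA exchange factor Ngef and the phosphatase Dusp4 were among the largest rises. Elastin and the collagen gene Col11a1 were among the largest falls. Of 10839 genes tested with limma, 2997 were higher and 2517 lower in src at an adjusted p under 0.05, which is 50.9% of the genes. Of these, 294 rose and 313 fell by at least 2-fold on the log2(RPKM + 1) scale. The median log2 fold change over all tested genes was 0.03. The balance of directions turned under each other scaling, with 2611 higher and 2846 lower (median of ratios), 2552 and 2914 (upper quartile) and 2410 and 2985 (trimmed mean of M-values), and with trends of gene length removed (2728 and 2775, or 2822 and 2846 with GC content). In 6804 genes (62.8%) the 3 vector values and the 3 src values did not overlap, where chance gives 10% for independent libraries. That chance share is higher if vector 1 and 2 are not independent, and genes that move together are not separate evidence. The count of 5514 called genes fell to 3641 without vector 1, to 3560 without vector 2 and to 2007 without replicate 1 of both groups. It rose to 6409 without src 2, and it was 1743 against a minimum fold change of 1.2. The 607 genes of at least 2-fold became 933 when limma voom was run on the reads recovered from the RPKM values.

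Prl2c3, a proliferin gene, showed the largest rise on the log2(RPKM + 1) scale, from 43.8 ± 66.1 to 956 ± 100 RPKM (SD, n = 3), a log2 change of 5.77 (SE 1.09, limma adjusted p = 0.0055). Prl2c2 rose by 5.07, but the members of this family are nearly identical and the handling of shared reads is not given in the sources used here. Ngef rose from 3.87 ± 5.89 to 73.5 ± 9.22 RPKM (log2 change 4.66) and Rgs16, a regulator of G protein signalling, from 3.52 ± 4.97 to 57.9 ± 24.7 RPKM (4.17). Siglec15 (3.90), Gpnmb (3.51), the MAP kinase phosphatase gene Dusp4 (3.35), the semaphorin gene Sema7a (3.21), the fatty acid transporter gene Slc27a1 (3.19) and Akr1c18 (3.16) completed the 10 largest rises. By the ratio of mean RPKM, src over vector, Gpnmb rose more than Prl2c3 (43 against 21.8). Much of the spread in the vector group came from vector 3, which held 120 RPKM of Prl2c3 against 5.95 and 5.30 in vector 1 and 2, and 10.7 RPKM of Ngef against 0.446 and 0.502. Without vector 3 the log2 change was 7.17 for Prl2c3, 6.17 for Prl2c2, 5.65 for Ngef, 5.05 for Rgs16, 4.77 for Siglec15 and 3.95 for Dusp4. Without vector 1 and without vector 2 it was 5.11 and 5.04 for Prl2c3, and without vector 1 it was 4.48 for Prl2c2. The value for Gpnmb was 2.74 without src 2 and 4.10 without src 3.

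Elastin, the core protein of elastic fibres, showed the largest fall on the log2(RPKM + 1) scale. Its gene Eln went from 283 ± 111 to 2.44 ± 1.67 RPKM (SD, n = 3), a log2 change of -6.38 (SE 0.42, limma adjusted p = 0.00013). By the ratio of mean RPKM, vector over src, Eln stood at 116 and Fhl1 at 120. Wisp2, which encodes a secreted matricellular protein of the CCN family, went from 151 ± 20 to 2.72 ± 0.715 RPKM (log2 change -5.36). Slurp1 fell by 4.69 on the log2 scale, and here vector 3 held 446 RPKM, above the other vector libraries. The LIM-domain gene Fhl1 (-3.94), the retinoic acid hydroxylase gene Cyp26b1 (-3.66), Ces2g (-3.49), Col11a1 (-3.40), Ccdc80 (-3.40), Prss23 (-3.23) and Srpx2 (-3.22) made up the rest of the 10 largest falls. All of these changes passed the threshold without any 1 of the 6 libraries, but without replicate 1 of both groups Prl2c3 (adjusted p = 0.051) and Gpnmb (0.052) did not.

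**Figure D2:**
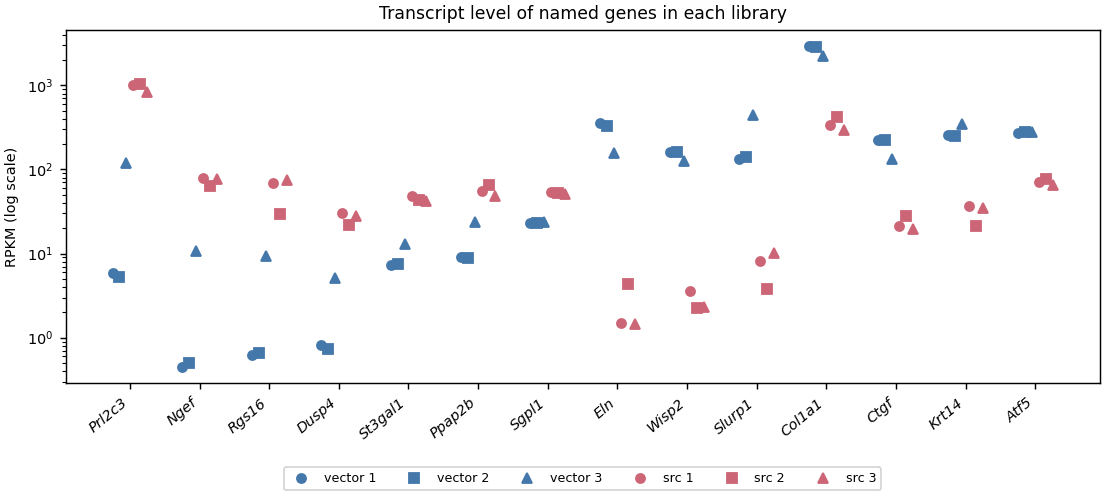
Transcript level in RPKM (log axis) of 14 named genes in each of the 6 libraries, blue for vector and red for src, with a marker shape for each replicate number. Vector 3 holds 120 RPKM of Prl2c3 and 10.7 RPKM of Ngef, between the other vector libraries and the src libraries, and 446 RPKM of Slurp1, above all others.

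The title of the series names sphingolipid metabolism in transformation, and 4 lists of sphingolipid genes were tested for it. Enzymes on either side of ceramide changed in both directions. The gene of sphingosine-1-phosphate lyase, Sgpl1, which irreversibly degrades sphingosine-1-phosphate, rose from 23.3 ± 0.539 to 52.9 ± 1.64 RPKM (SD, n = 3; log2 change 1.15, SE 0.05, limma adjusted p = 6e-05). The sialyltransferase gene St3gal1 rose by 2.19 and the lactosylceramide synthase gene B4galt5 by 1.61, while Smpd3, which encodes a neutral sphingomyelinase, fell by 1.44 on the log2 scale. Of 90 genes written in the 4 lists, 88 were in the table and 60 were tested, of which 20 rose, 10 fell and 30 did not pass. The called share was 50%, against 50.9% of all tested genes. Adjusted over the list alone, with the 4 lists pooled, the counts were again 20 and 10. At least 2-fold changes numbered 5 rises and 2 falls. Against a minimum fold change of 1.2 there were 12 rises and 3 falls. Leaving out replicate 1 of both groups gave 14 and 3, and leaving out src 2 gave 24 and 15. None of the 4 lists passed limma camera, which compares a list with all other genes (adjusted p = 0.46, 0.72, 0.59 and 0.31 for ceramide synthesis, ceramide and sphingosine turnover, complex sphingolipid synthesis and lysosomal breakdown). The fry rotation test does not compare a list with other genes. By fry, ceramide synthesis, complex sphingolipid synthesis and lysosomal breakdown passed, all upward (adjusted p = 0.0015, 0.0023 and 0.0099). Ceramide and sphingosine turnover did not (fry adjusted p = 0.85). Fry was run with the main scaling only. Under each other scaling the sphingolipid calls were 19 rises and 13 falls, so the upward direction may depend on the scaling.

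Among the 12 tested genes of ceramide synthesis, 3 rose, 1 fell and 8 did not pass, and adjusted over the list alone 3 rose and 0 fell. The ceramide synthase gene Lass6 (Cers6) rose from 5.82 ± 0.220 to 9.86 ± 0.705 RPKM (log2 change 0.67). Lass2 (Cers2) rose by 0.44 and Sptlc2, a subunit of serine palmitoyltransferase, by 0.31, while its regulator Ormdl3 fell by 0.17 on the log2 scale. Degs1, the desaturase gene of the last step to ceramide, stood at 60 ± 0.665 RPKM in vector and 61.3 ± 0.443 RPKM in src (adjusted p = 0.61). The calls of Lass2 and Ormdl3 were lost without vector 1 (adjusted p = 0.052 and 0.13) and without vector 2 (0.054 and 0.16), and that of Ormdl3 also without src 1 (0.059) or src 3 (0.12).

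In ceramide and sphingosine turnover, 4 of 19 tested genes rose and 5 fell, with the same counts adjusted over the list alone. Besides Sgpl1, the lipid phosphate phosphatase gene Ppap2b rose from 14 ± 8.66 to 56.8 ± 8.38 RPKM (2.08), with 24.0 RPKM in vector 3. Its relative Ppap2a fell from 51.5 ± 3.52 to 29.3 ± 3.16 RPKM (-0.80). The third member, Ppap2c, stood at 36.1 ± 10.7 RPKM in vector and at 36.7, 0.717 and 43.7 RPKM in src 1, 2 and 3 (adjusted p = 0.38). Sphingosine kinase changed in Sphk1, which rose from 2.64 ± 0.258 to 4.96 ± 0.923 RPKM (0.70), whereas Sphk2 stood at 11 ± 0.273 and 11.4 ± 0.777 RPKM (adjusted p = 0.51). Of the sphingosine-1-phosphate receptors, S1pr3 fell from 25 ± 5.24 to 10.8 ± 2.90 RPKM (-1.14), S1pr2 rose by 0.29, and S1pr1 stood at 2.62 ± 0.773 and 2.75 ± 0.982 RPKM (adjusted p = 0.89). Smpd3 went from 4.78 ± 0.195 to 1.14 ± 0.311 RPKM, the acid sphingomyelinase gene Smpd1 fell by 0.28 and the ceramidase gene Acer3 by 0.38 on the log2 scale. The call of S1pr2 was lost under each other scaling, and it was lost without vector 1, 2 or 3, src 1 or src 3 (adjusted p = 0.077, 0.098, 0.11, 0.092 and 0.093).

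In the synthesis of complex sphingolipids, 8 of 17 tested genes rose and 3 fell, and adjusted over the list alone 8 rose and 5 fell. The median log2 change was 0.01 and the mean 0.27. St3gal1, whose enzyme adds sialic acid to glycoproteins and gangliosides, rose from 9.26 ± 3.27 to 44.4 ± 3.32 RPKM, and B4galt5 from 18.7 ± 5.95 to 58.1 ± 9.67 RPKM. Vector 3 held 13.0 and 25.6 RPKM of them, the highest of the vector libraries. Rises below 2-fold were found for the sphingomyelin synthase gene Sgms2 (0.57), the glucosylceramide synthase gene Ugcg (0.41), the ganglioside enzyme genes St6galnac6 (0.62), B4galnt1 (0.41) and St6galnac4 (0.30), and Samd8 (0.37). The glycolipid transfer protein gene Gltp fell from 40.1 ± 2.45 to 29.4 ± 0.822 RPKM (-0.44), and St3gal2 and St3gal3 fell by 0.22 and 0.19. St3gal5, the gene of the enzyme that makes the ganglioside GM3, stood at 25.2 ± 0.322 and 19.3 ± 4.02 RPKM (-0.39, adjusted p = 0.057). It passed without src 1 (-0.51, 0.029) and without src 2 (-0.22, 0.014), and under each of the 3 other scalings. The calls of St6galnac4, St3gal2 and St3gal3 were lost without vector 1 (adjusted p = 0.084, 0.12 and 0.085) and without vector 2 (0.085, 0.11 and 0.076). That of St6galnac4 was also lost without src 1 (0.071), those of St3gal2 and St3gal3 without src 3 (0.082 and 0.064), and that of St3gal2 without vector 3 (0.097).

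Of 12 tested genes of lysosomal sphingolipid breakdown, 5 rose and 1 fell, with the same counts adjusted over the list alone. The alpha-galactosidase gene Gla rose from 4.17 ± 0.629 to 9.57 ± 0.178 RPKM (1.04), and the saposin precursor gene Psap from 273 ± 16.5 to 426 ± 20 RPKM (0.64). The sialidase gene Neu1 rose by 0.60 and the hexosaminidase subunit gene Hexa by 0.38 on the log2 scale. Of the 28 calls named from the 4 lists, 22 passed in each of the 6 fits that left out 1 library, and 6 did not. Of these 22, the calls of Sptlc2, S1pr3, Smpd1, Acer3, Samd8 and Hexa were lost without replicate 1 of both groups (adjusted p = 0.079, 0.056, 0.088, 0.092, 0.060 and 0.097), and that of Acer3 also without replicate 3 (0.066).

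**Figure D3:**
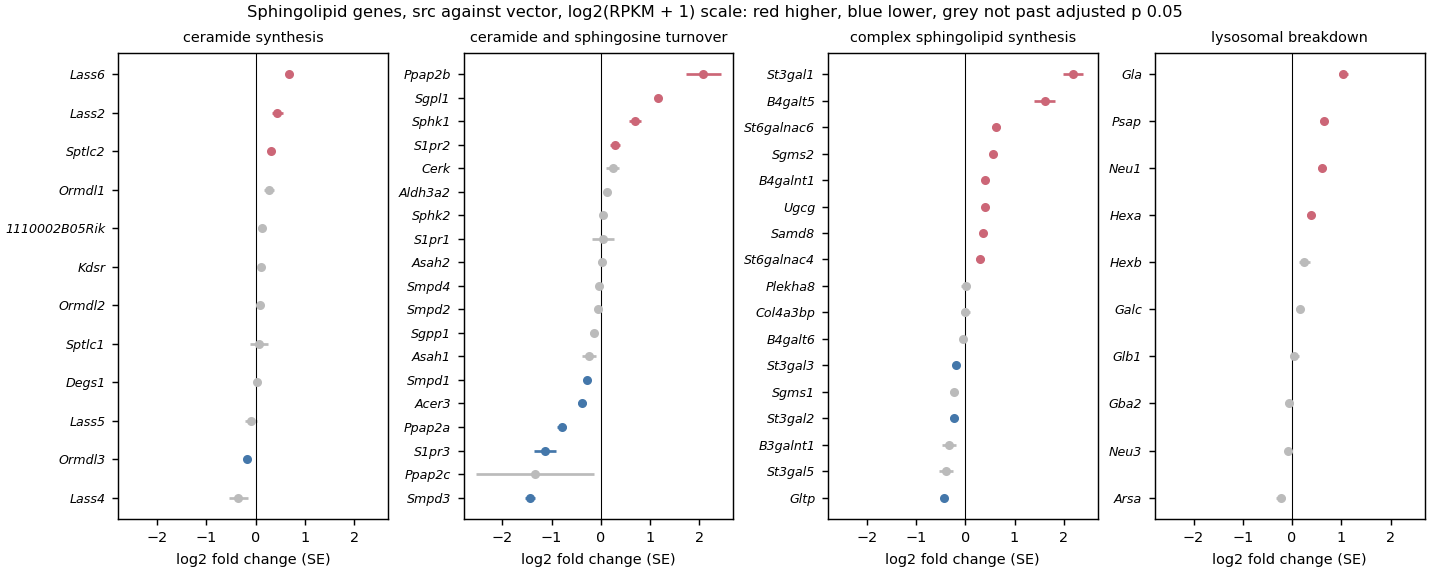
Log2 fold change of src against vector on the log2(RPKM + 1) scale, with its SE, for tested genes of the 4 sphingolipid lists, each list in its own panel. Red points rose (19 drawn), blue points fell (9 drawn) and grey points (30) did not pass an adjusted p of 0.05. Called genes that the text does not name are not drawn.

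Extracellular matrix genes fell together. Of 39 tested genes of this list, 32 fell and 5 rose, with 33 and 6 adjusted over the list alone, and the median log2 change was -1.38 (camera adjusted p = 3.3e-08; adjusted p = 0.65 with an estimated correlation). The fibrillar collagen genes led by level: Col1a1 fell from 2670 ± 389 to 350 ± 63.7 RPKM (log2 change -2.93) and Col1a2 from 2160 ± 349 to 466 ± 38.2 RPKM (-2.20). Col1a1 made up 1.26% of the reads in vector and 0.165% in src. Col5a2 fell by 2.83 and the microfibril gene Mfap5 by 2.29 on the log2 scale. The 5 that rose were the proteoglycan genes Dcn (2.25) and Vcan (0.77), Thbs2 (2.03), the tenascin gene Tnc (1.60) and the laminin gene Lamb1 (0.70). Dcn stood at 5.31 ± 0.797 RPKM in vector and 30.5 ± 12.3 RPKM in src. Vector 3 held 2218 RPKM of Col1a1 and 1755 RPKM of Col1a2, the lowest of the vector libraries.

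Cholesterol synthesis genes rose together. Of 24 tested genes, 20 rose and 0 fell, with the same counts adjusted over the list alone (median log2 change 0.60, camera adjusted p = 3.2e-07; adjusted p = 0.65 with an estimated correlation). The lanosterol synthase gene Lss rose from 18.1 ± 1.30 to 36.3 ± 2.07 RPKM (0.97), the isomerase gene Idi1 from 18.3 ± 0.900 to 36.6 ± 3.52 RPKM (0.96), and the farnesyl diphosphate synthase gene Fdps from 63.6 ± 2.99 to 113 ± 2.71 RPKM (0.82). Hsd17b7 rose by 0.81 and Acat2 by 0.72. Srebf2, the gene of the transcription factor of this pathway, stood at 96.2 ± 11.9 and 103 ± 6.83 RPKM (adjusted p = 0.42, and 0.025 without replicate 3 of both groups). The list of fatty acid synthesis did not pass (10 of 20 rose and 4 fell, 10 and 4 adjusted over the list alone, camera adjusted p = 0.60). Within it Fasn rose from 77.4 ± 8.14 to 144 ± 9.62 RPKM (0.89), the acyl-CoA synthetase gene Acsl4 by 1.22, the desaturase gene Scd2 by 0.92, Elovl6 by 0.84 and Acly by 0.64, while Fads3 fell by 1.1 and Me1 by 0.55 on the log2 scale.

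Of 20 tested glycolysis genes, 15 rose and 2 fell, with the same counts adjusted over the list alone (median log2 change 0.66, camera adjusted p = 0.0012; adjusted p = 0.85 with an estimated correlation). The glucose transporter gene Slc2a1 rose from 98.5 ± 21.4 to 207 ± 4.97 RPKM (1.09), Hk2 from 10.8 ± 1.08 to 22.5 ± 2.49 RPKM (0.99), and Aldoa from 378 ± 65.4 to 703 ± 5.16 RPKM (0.91). Tpi1 rose by 0.86 and Hk1 by 0.54. The 2 genes that fell were Pfkfb3 (-0.34) and Pfkp (-0.27), whose calls were lost without replicate 1 of both groups (adjusted p = 0.066 and 0.067), that of Pfkp also without replicate 3 (0.052). Vector 3 held 123 RPKM of Slc2a1 and 453 RPKM of Aldoa, the highest of the vector libraries.

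Genes downstream of the ERK kinases rose for the most part. In this list 21 of 31 tested genes rose and 5 fell, with 21 and 6 adjusted over the list alone (median log2 change 0.94, camera adjusted p = 0.00081; adjusted p = 0.65 with an estimated correlation). The ETS factor genes Etv4, Etv1 and Etv5 rose by 2.16, 2.06 and 1.61, Etv4 from 6.82 ± 1.1 to 33.8 ± 3.05 RPKM. The feedback inhibitor genes Spry2 (1.44), Spred1 (1.13) and Dusp4 also rose. Among those that fell were Egr1 from 43.2 ± 6.59 to 13.0 ± 2.86 RPKM (-1.67), Dusp1 (-1.32) and Jund (-1.13). Junb stood at 40.6 ± 1.01 and 38.1 ± 9.47 RPKM (adjusted p = 0.60).

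Genes of the unfolded protein and amino acid responses fell, with 21 of 35 tested genes lower and 2 higher in src and the same counts adjusted over the list alone (median log2 change -0.54, camera adjusted p = 1.1e-05; adjusted p = 0.12 with an estimated correlation). For this list the estimated correlation was -0.01, and the unadjusted camera p with it was 0.005. The transcription factor gene Atf5 fell from 276 ± 4.47 to 71.2 ± 5.91 RPKM (-1.94), the serine synthesis genes Psph and Phgdh fell by 1.41 and 1.01 on the log2 scale, and the amino acid transporter subunit gene Slc3a2 fell from 144 ± 7.48 to 55.3 ± 2.98 RPKM (-1.37). Herpud1, which acts in the degradation of proteins from the endoplasmic reticulum, fell by 1.96. The chaperone genes Hspa5 (253 ± 5.19 and 230 ± 13.0 RPKM, adjusted p = 0.094) and Calr (502 ± 38.1 and 442 ± 12.8 RPKM, adjusted p = 0.068) did not pass. Hspa5 passed without src 2 (-0.18, adjusted p = 0.020), Calr without vector 3 (-0.24, 0.011), and both under each other scaling. The 2 that rose were Pdia3 (0.29, adjusted p = 0.075 without replicate 1 of both groups) and Cebpb (0.55), and Cebpb lost its call without any 1 of the 5 libraries vector 1, vector 2, src 1, src 2 and src 3 (adjusted p from 0.057 to 0.096).

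**Figure D4:**
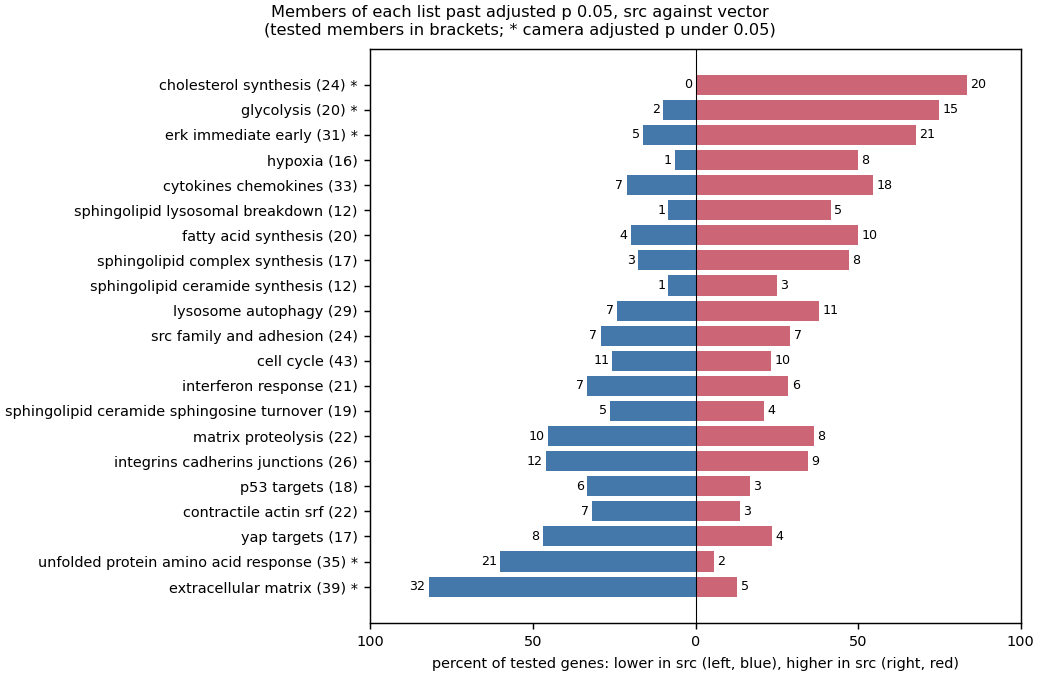
Share of the tested genes of each of 21 lists that fell (blue, left) or rose (red, right) in src at an adjusted p under 0.05, with the number of genes at the end of each bar and the number tested in brackets. The bar of the extracellular matrix reaches furthest to the left (32 of 39) and that of cholesterol synthesis furthest to the right (20 of 24).

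The remaining lists did not pass camera, and most had members that moved strongly in both directions. Of 22 contractile genes, 3 rose and 7 fell, the same adjusted over the list alone (camera adjusted p = 0.48). Tagln fell from 188 ± 59.2 to 24.6 ± 8.78 RPKM (-2.89), the smooth muscle actin gene Acta2 by 1.95 and the caldesmon gene Cald1 by 0.94 on the log2 scale, while Flna stood at 285 ± 3.43 and 287 ± 22.7 RPKM (adjusted p = 0.92). Of 17 targets of the co-activator YAP, 4 rose and 8 fell, with 4 and 9 adjusted over the list alone (camera adjusted p = 0.099, and 0.017 among genes of at least 5 RPKM in 3 libraries). With an estimated correlation, run for the main filter only, the camera adjusted p was 0.65. Ctgf fell from 193 ± 52.3 to 23.1 ± 4.4 RPKM (-2.98), Nuak2 by 1.75 and Amotl2 by 1.62. Of 24 genes of Src family kinases and adhesion, 7 rose, among them the transduced gene Src itself, and 7 fell, the same adjusted over the list alone (camera adjusted p = 0.78). The caveolin gene Cav1 fell from 171 ± 6.85 to 67.3 ± 8.42 RPKM (-1.34), and the caveolar coat genes Ptrf and Prkcdbp fell by 0.66 and 0.46. The focal adhesion gene Pxn rose by 0.61 and Cttn, which encodes the Src substrate cortactin, by 0.36. Of the related kinase genes, Frk rose from 1.80 ± 0.245 to 3.56 ± 0.998 RPKM (0.69, adjusted p = 0.011, and 0.054 without replicate 3 of both groups), Yes1 rose (0.27) and Fyn fell (-0.24). Without replicate 1 of both groups the calls of Cttn, Yes1 and Fyn were lost (adjusted p = 0.055, 0.074 and 0.11).

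Genes of matrix breakdown, adhesion receptors and secreted factors moved in both directions. Of 22 tested matrix protease genes and their inhibitors, 8 rose and 10 fell, the same adjusted over the list alone (camera adjusted p = 0.79, direction down; median log2 change -0.06, mean 0.01). The urokinase receptor gene Plaur rose from 44.5 ± 7.85 to 124 ± 5.32 RPKM (1.48), the cathepsin gene Ctsb by 1.47 and the membrane protease gene Mmp14 by 0.88, while Adamts5 fell by 1.98 and Mmp2 by 1.14 on the log2 scale. Of 26 integrin, cadherin and junction genes, 9 rose and 12 fell, the same adjusted over the list alone (camera adjusted p = 0.60). Alcam (2.0), Cd44 (1.37) and Itga6 (1.02) rose, and Itga11 (-2.17) and Itgb5 (-1.49) fell. Of 33 cytokine and growth factor genes, 18 rose and 7 fell, the same adjusted over the list alone (camera adjusted p = 0.17). Kitl rose from 24.0 ± 2.70 to 67.2 ± 2.37 RPKM (1.45) and Fgf2 from 1.23 ± 0.0812 to 5.44 ± 1.31 RPKM (1.51), and Igfbp7 fell from 102 ± 11.9 to 25.8 ± 2.29 RPKM (-1.95).

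Cell cycle genes were split. Of 43 tested, 10 rose, 11 fell and 22 did not pass, the same adjusted over the list alone (camera adjusted p = 0.97, direction down; median log2 change 0.05). The cyclin gene Ccnd1 rose from 114 ± 17.1 to 197 ± 19.7 RPKM (0.78) and Cdk4 by 0.65, Ccnd2 fell by 1.09 on the log2 scale, and Top2a stood at 72.0 ± 6.85 and 73.8 ± 1.23 RPKM (adjusted p = 0.69). Of 16 hypoxia genes, 8 rose and 1 fell (camera adjusted p = 0.14), with Bnip3 (1.93) and Hif1a (0.67) among the rises and Adm (-1.60) as the fall. Of 18 targets of p53, 3 rose and 6 fell (camera adjusted p = 0.14), with Mdm2 at 0.70 and Plk2 at -1.88. Of 29 genes of lysosomes and autophagy, 11 rose and 7 fell (camera adjusted p = 0.60), with Cd63 at 0.93 and Tfeb at -1.07. Of 21 interferon response genes, 6 rose and 7 fell (camera adjusted p = 0.84, direction down; median log2 change 0.07), with B2m at 0.96 and Isg15 at -1.97. For these last 4 lists the counts were the same adjusted over the list alone.

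Markers of other cell types were mostly too low to test. Of 15 adipocyte markers 3 were tested, and 1 rose and 1 fell, the latter being Lpl (-1.90). Of 16 leukocyte markers 3 were tested, with Cd14 (0.81) and Cd68 (0.26) higher and Lyz2 (-1.35) lower, and the call of Cd68 was lost without vector 1 (adjusted p = 0.059). Of 15 bone and cartilage markers 4 were tested, with 1 higher and 1 lower (Comp, -0.94), and of 16 neural and glial markers 4 were tested, with 1 higher and 1 lower (S100b, -1.09). Of 14 endothelial markers 2 were tested and Cdh5 rose (1.06), reaching 1.44 ± 0.195 RPKM, and of 15 skeletal muscle markers Acta1 alone was tested and did not pass (adjusted p = 0.18; -1.66 and 0.0010 without src 3). Of 15 epithelial markers the keratin gene Krt14 alone was tested, and it fell from 284 ± 57.4 to 31.1 ± 8.59 RPKM (-3.17). Adjusted over the list alone the counts were the same except for the adipocyte list, with 2 higher.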

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

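Trimmed mean of M-values scaling and the averaging of vector 1 and 2 were chosen after seeing the data; the other alternatives were fixed beforehand, with the stricter filter restated from CPM to RPKM once the unit was known. The 5514 genes called by limma ranged from 2007 to 6409 when libraries were left out, with 3641 without vector 1, 3560 without vector 2, 2007 without replicate 1 of both groups and 6409 without src 2. The count was 3624 with vector 1 and 2 averaged and 1743 when tested against a minimum fold change of 1.2, of which all 1743 were among the 5514. Under the other scalings 5395 to 5466 genes were called, the share of higher genes went from 54.4% to between 44.7% and 47.8%, and the median log2 change from 0.03 to between -0.02 and -0.01. No gene called both here and in any alternative changed direction. Genes called with at least 2-fold changes numbered 933 with limma voom on the recovered reads, where the fold of low genes is not damped by adding 1 RPKM, and 485 to 654 with libraries left out. The sphingolipid count of 30 ranged from 17 to 39 with libraries left out (17 without replicate 1 of both groups, 39 without src 2), and the 348 called genes of all lists from 218 to 381 (218 without replicate 1 of both groups). Against the minimum fold change of 1.2 the sphingolipid count was 15 (12 higher and 3 lower), and 218 genes of all lists were called. The Src change stayed past the threshold in each alternative run, from 1.19 to 1.62 with libraries left out. The same 5 lists passed camera in each of 24 settings with the preset correlation, and YAP targets also passed in 2 of them. These settings include the main fit and the minimum fold change of 1.2, which leaves camera unchanged. With an estimated correlation 0 lists passed. The fry test, which does not compare a list with other genes, called 16, sphingolipid lists among them.

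Same-numbered vector and src libraries did not deviate together from their group means (correlations of 0.00, 0.01 and -0.02). Vector 3 and src 2 dominate these deviations, so a modest effect shared by same-numbered libraries need not show. Whether the numbers pair the samples therefore stays open. With the replicate block 4789 genes were called, the lists past camera were 6, with YAP targets at an adjusted p of 0.048, and 27 sphingolipid genes passed. The estimated correlation was not run with the block, and without the block it gave YAP targets a camera adjusted p of 0.65. Length and GC removal, with and without the block, left between 4753 and 5668 genes. For single genes named in the text, 3462 values over all alternatives kept direction and side of the threshold, 87 lost and 25 gained a call, and none reversed. Chosen beforehand but not run were the DESeq2 test and a column of unique reads, since the file holds neither counts nor such a column. The count model that the design named for a table of counts, edgeR, was not run either. Both count models could have been run on the recovered reads. Scaling by library size alone and limma on log2(RPKM + 1) are the main test itself.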

Other observations

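All tests in this part were chosen only after the results they bear on had been seen. The annotation in the deposited table held 551 biological process terms of 15 to 300 tested genes, and 3 passed limma camera with the preset correlation: cholesterol biosynthesis (adjusted p = 0.0059), tRNA aminoacylation (0.014) and RNA splicing (0.038). With an estimated correlation each had an adjusted p = 0.99. The estimated correlations were 0.27, 0.01 and 0.04 in the same order, with unadjusted camera p = 0.13, 0.016 and 0.086. Of 35 tested genes annotated to tRNA aminoacylation, 19 fell, 3 rose and 13 did not pass. Gars, the glycyl-tRNA synthetase gene, went from 190 ± 9.27 to 112 ± 11.5 RPKM (SD, n = 3; log2 change -0.76), Lars fell by 0.73, Yars by 0.70 and Nars by 0.65 on the log2 scale, while Rars rose from 52.7 ± 3.20 to 78.1 ± 3.47 RPKM (0.56). Among synthetase symbols without a final 2, which are mostly the cytosolic enzymes, 12 of 17 fell and 2 rose (median -0.36), and among those ending in 2, mostly the mitochondrial enzymes, 7 of 17 fell and 0 rose (median -0.15), with Cars2 at -0.55. The difference between both sets was not tested.

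Of 186 tested RNA splicing genes, 80 rose, 7 fell and 99 did not pass, with a median log2 change of 0.14 (camera adjusted p = 0.038; 0.99 with an estimated correlation). Under trimmed mean of M-values scaling these counts were 64 and 15. The spliceosome genes Ddx39b (117 ± 7.64 to 176 ± 7.34 RPKM, 0.58) and Snrnp200 (0.36, adjusted p = 0.060 without replicate 1 of both groups) rose, and Ddx41 rose by 1.41. The genes of these 2 terms lie outside the rule for named genes and were chosen after their values were seen.

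Src 2, the src library with the least Src transcript (39.0 RPKM), lay as far from the vector libraries on the first principal component (27.7) as src 1 and 3 (27.4). It differed at least 2-fold from src 1 and 3 in 62 genes that these others shared within 0.5 on the log2 scale, 42 higher and 20 lower. Picked for this difference, Glipr1 stood at 22 RPKM in src 2 against 1.93 and 1.2 in src 1 and 3, Dlk1 at 109 against 39.0 and 46.0, and Usp14 at 59.5 against 21.2 and 21.9. Ppap2c stood at 0.717 against 36.7 and 43.7, Cyba at 5.47 against 25.5 and 20.2, Msln at 7.70 against 29.0 and 26.1, and Ezr at 20.7 against 52.4 and 50.9.

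Vector 3 lay between the other vector libraries and the src libraries, and the tables argue against lower depth, since vector 1 and 2 thinned to its depth correlated with the src mean at no more than 0.9527, against 0.9669 for vector 3, and against a wrong label, since its lowest correlation with a vector library was 0.9914 and its highest with a src library 0.9658. A candidate explanation is Src-transduced material in vector 3: in 10 genes whose level in vector 1 and 2 was under 1% of that in src, among them Prl2c3, Ngef and Siglec15, vector 3 held a median of 0.131 of the src level, and the SD of the log2 of this share, 0.54, was below that of log2 ratios between src libraries over the same genes (0.68 to 1.1). Src 2, which stood apart, enters each of these ratios, and the shares went from 0.0657 to 0.193. The comparison is therefore loose and does not show a single share. Of the 47 other genes at least 5-fold higher in src, with shares from 0.0185 to 0.638 (median 0.151), 14.9% lay outside the range from 0 to the highest share of the 10 genes (0.193), widened by the gap between vector 1 and 2, which leaves this explanation open. One share of such material in a pool otherwise like vector 1 and 2 does not account for the genes at least 5-fold lower in src, of which 81.8% of 66 lay outside that range, as Slurp1 did. The range allows only for the gap of this close pair, so ordinary differences between pools can also place genes outside it. The Src transcript stood at 23.6 RPKM in vector 3, against 16.2 and 16.1 in vector 1 and 2 and a mean of 52.1 in src. A pool of vector cells that itself differs from the others, with or without such material, stays open and was not tested.

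Vector 1 and 2 were closer to each other than any other pair. Their chi-square was 3.47 per gene, where counting error alone would give 1, and 15.1% of their genes passed the 95% point of chance, while the pair of src 1 and 3, the next closest, had 26.4 and 42.6%. Runs of one library can exceed counting error by an amount that is not known here. Whether both came from one library, one RNA or one culture cannot be told apart from a close pair of pools by these values, while the design text describes independent cultures. The fit that averages them called 3624 genes.

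Going by the authors' deposited values, 1374 genes had reads only in src libraries and 440 only in vector libraries. With all libraries thinned to the depth of vector 3, over 20 draws, the counts averaged 1238 and 526 and their ratio, taken in each draw, averaged 2.36 (2.26 to 2.46), so that depth alone does not account for it. These genes held a median of 2 reads over the 3 src libraries, 199 of them had reads in all 3 src libraries (35 for vector), and 7 reached a mean of 0.5 RPKM. Whether low-level expression or stray reads give these values was not tested.

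With 3 libraries against 3 there are 10 splits, too few for a share under 0.05. The real split gave 5514 called genes, 607 of at least 2-fold, 30 sphingolipid genes and 348 genes of all lists, and the highest of the other splits gave 0 for each, so that 1 split gave counts as large. For lists past camera the real split gave 5 and the highest of the others 6, and 6 of the 10 splits gave at least 5. Each other split mixes vector and src libraries, so that the difference between the groups enters its spread and part of its contrast. The other splits therefore do not show the level of chance for the genes or for the lists.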
